A study of Rattus norvegicus with 42 samples.

How the data were processed

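RNA from the left testis of male rats was measured on single-colour (Cy3) Agilent rat whole genome arrays, 1 array per rat. Rats received flutamide or vehicle by gavage for 28 days, at 0, 0.2, 1, 6 or 30 mg/kg/day. The files held 42 arrays out of 10 rats per group, and why some rats have no array is not given in the sources used here. Every replicate is 1 rat, so the spread within a group is between animals, and the number of arrays limits the precision.

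The intensity values of each array were made by Agilent Feature Extraction 10.5.1.1 per the file headers, as background-subtracted and detrended signals of 45018 spots, with a surrogate value for spots not above background and no scaling between arrays. Mean signals and local background medians were also deposited for 40 of the 42 arrays. The log2 values of the series matrix were deposited by the authors for 41090 probes. Tested on the files, the differences between its columns matched those of the log2 intensities up to a constant per array (r = 0.9997 to 0.99997), its column medians lay between -0.083 and 0.070, and 100% of probes had a median within 0.001 of 0 over 8 controls, rat 2 being the control outside that median. The authors' deposited list of dose-responsive probes was used for its 1585 probe names. Its 42 columns of values per sample carry names that match no sample label and were not used here.

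Here, the intensities were taken to log2, outlier-marked spots were left out, spots of the same probe were averaged, and each array was shifted by its 75th percentile. Probes well above background on at least 7 of the 42 arrays were tested, 31839 of 41012, and 23127 were well above background on all arrays. Gene names came from the array files, updated through reference tables of symbols and synonyms, and positions refer to the rn4 build that the file headers name. R 4.3.3 with limma 3.58.1 fitted the 5 group means, with moderated statistics and Benjamini-Hochberg adjustment over the tested probes within each contrast, and a two-sided adjusted p under 0.05 counted as a change. The contrasts were each dose against control, 30 against 6 mg/kg/day, the slope over dose scores 0 to 4, and an F-test over the 4 doses. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

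The 23 gene lists were androgen synthesis, cholesterol synthesis and uptake, Leydig cell identity, cAMP and LH response, Sertoli cell, androgen dependent Sertoli genes, spermatogonia, meiotic spermatocyte, round spermatid, elongating spermatid, peritubular myoid and smooth muscle, vascular endothelium, macrophage, lymphocyte, erythroid cell, epididymis, adipose tissue, mitotic cell cycle, aryl hydrocarbon receptor and xenobiotic, oxidative stress and glutathione, apoptosis, immediate early and heat shock, and gonadal hormone receptors and feedback. They were written with the settings, the contrasts and the rule for naming genes before the data were examined. Some members of the lists are not reported here by name. Each gene was represented by its passing probe with the highest mean over arrays, and lists with at least 3 measured members were tested with camera (limma, preset correlation 0.01), also with an estimated correlation and with fry, and adjusted over the lists. The score of a list in a rat is the mean over members of the log2 value less the control mean, and scores were compared by exact two-sided permutation tests. For a dose with calls, the rule named the 10 rising and 10 falling genes of largest log2 fold among probes past the threshold whose name is a gene symbol, with 1 probe per gene, and the trend used its slope. List members may be named as well, whether or not they passed. A fold of a gene named by the rule against a group not well above background on every array is given as a lower bound, and where both groups lie near background no fold is given.

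Depth is described by the share of spots well above background per array. On simulated data with the arrays' own spread, 50 genes per size were changed 1.2-fold, 1.5-fold, 2-fold or 3-fold, and limma called 14% to 96% of them at 30 mg/kg/day and 22% to 98% at 6 mg/kg/day. Probes varied independently there and all sizes were changed together, so a dose with few changed genes may have a lower share called. The correlation of log2 folds between doses was compared with 100 random regroupings of residuals, and with controls split by odd (5) and even (4) rat numbers. The residuals were scaled up for the fitted group means, a correction made after simulated values were first seen.

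The slide of each array and its position came from the file headers. Results were also computed with slide as a block, with the 2 series of slide numbers as a block and within each series. Further alternatives were quantile normalization, centring on the median, normexp background correction on the 40 arrays with mean signals, the series matrix values, no filter and a stricter filter, outlier-marked spots kept, rat number as a block, array weights, a variance trend with robust estimation, only the groups compared in the fit, an adjusted p under 0.01, a change of at least 1.5-fold, a residual principal component as a covariate, other dose scores, the median over the probes of a gene, and each rat left out in turn. The slide series alternatives, the opposite split of the controls and leaving out rats 3 and 7, or 3, 7 and 9, of 30 mg/kg/day were chosen after seeing the data. Phenotypic measurements of the study, such as hormone levels and histology, were not analysed here.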

Results

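Testis RNA was measured on 42 whole genome arrays from male rats given flutamide, a non-steroidal blocker of the androgen receptor, or vehicle. Rats were 7 weeks old when dosing began and were dosed by gavage once a day for 28 days. The arrays covered 9 control rats, 8 rats at 0.2 mg/kg/day, 7 at 1 mg/kg/day, 9 at 6 mg/kg/day and 9 at 30 mg/kg/day, out of 10 rats per group in the study. Each array held the left testis RNA of 1 rat, so every replicate is an animal. The title of the series asks for a dose of an anti-androgen without an effect on the testis, and each dose was compared with control to describe which genes differed there.

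Between 58.4% and 78.2% of the spots of an array were well above background. The group means were 70.0% ± 5.40 (SD, n = 9) in controls, 72.0% ± 5.05 (n = 8) at 0.2, 69.1% ± 6.02 (n = 7) at 1, 72.7% ± 4.76 (n = 9) at 6 and 71.4% ± 4.62 (n = 9) at 30 mg/kg/day. The arrays came from 13 slides in 2 series of slide numbers, with 26 arrays in series 1 and 16 in series 2, and every group had arrays in both. Series 1 arrays had 58.4% to 71.8% of spots well above background and series 2 arrays 73.3% to 78.2%. The mean correlation of an array with the others of its group was lowest at 30 mg/kg/day (mean 0.986), where rat 7 had the lowest value, 0.981, followed by rats 3 and 9, both at 0.984.

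At 30 mg/kg/day, the testis held more RNA for several genes of the route from cholesterol to testosterone, though not for Hsd17b3, which forms testosterone itself. Cyp11a1, which cleaves the cholesterol side chain, rose by 2.59 ± 0.175 on the log2 scale (SE, n = 9 and 9 rats; adjusted p = 3.29e-14). Star, which brings cholesterol into the mitochondrion, rose by 2.32 ± 0.222 (adjusted p = 3.22e-10), Cyp17a1 by 2.19 ± 0.166 (adjusted p = 7.28e-13) and Hsd3b1 by 2.10 ± 0.179 (adjusted p = 1.50e-11). Scarb1, the receptor that takes up cholesterol from high density lipoprotein, rose by 2.45 ± 0.176 (adjusted p = 1.52e-13). These rises stood within a response of 1565 probes higher and 1139 lower than control.

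Of the 13 measured members of the androgen synthesis list, 10 rose, and 11 rose and 1 fell when adjusted over the list alone. Hsd3b2 rose by 2.04 (0.71 at another probe, adjusted p = 0.0126), Fdx1 by 1.03 and Fdxr by 0.82, the last 2 being the electron carriers of the mitochondrial enzymes, and Tspo, Cyb5a and Scp2 rose by 0.55, 0.41 and 0.41. Hsd17b3, which makes testosterone from androstenedione, was not past the threshold (log2 fold -0.44, adjusted p = 0.269), nor were Por (log2 fold 0.15) and Stard6 (log2 fold -0.13). The list median was 0.82 (camera adjusted p = 6.45e-25; adjusted p = 4.26e-09 with an estimated correlation). The list score, the mean log2 difference of its members from the controls, was 1.08 ± 0.155 (SD, n = 9), above every control in 9 of 9 rats (exact permutation p = 4.11e-05, the smallest that the design can give; adjusted p = 1.89e-04). Within slide series 1 the difference was 1.06 (exact p = 0.00216), within series 2 it was 1.11 (exact p = 0.0286), both the smallest possible, and with slide as a block it was 1.096.

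**Figure D1:**
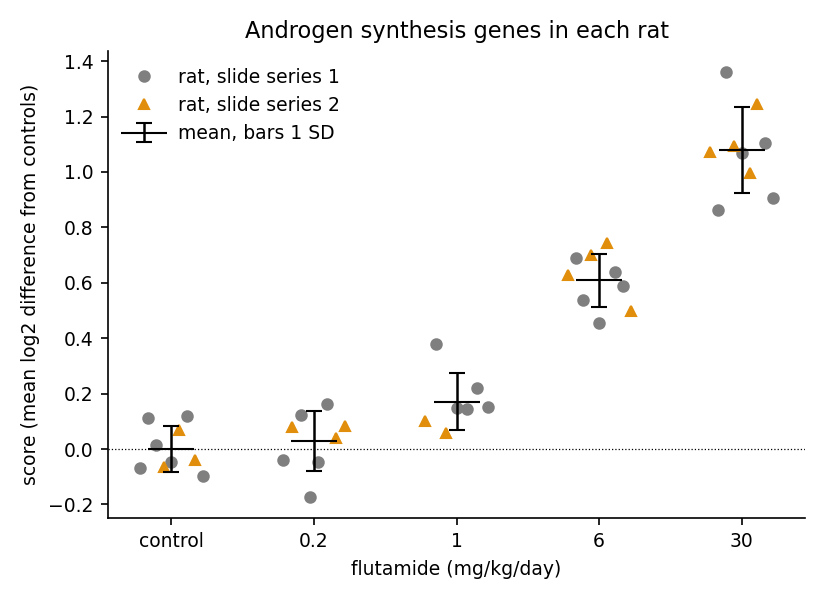
Score of the androgen synthesis list in each rat (vertical axis, mean log2 difference of 13 genes from the control mean) against dose in mg/kg/day, with group means and bars of 1 SD. Circles and triangles mark the 2 slide series. The mean was 1.08 at 30, 0.61 at 6, 0.17 at 1 and 0.03 at 0.2 mg/kg/day.

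Genes of cholesterol synthesis and uptake rose in part. Of 24 measured members 12 rose, also when adjusted over the list alone, and the list median was 0.21 (camera adjusted p = 2.98e-16; adjusted p = 5.44e-05 with an estimated correlation). The largest rise was that of Scarb1 (2.45), followed by Msmo1 at 1.28 ± 0.0936 (SE, n = 9 and 9), Ebp at 1.26 ± 0.0834, Dhcr7 at 1.16 ± 0.0965 and Nsdhl at 1.14 ± 0.114, with smaller rises in others such as Acat2 (1.00), Insig1 (0.41), Stard4 (0.40), Lss (0.35), Hsd17b7 (0.30) and Mvk (0.28). Hmgcs1, Idi1 and Srebf2 had log2 folds of -0.01, 0.09 and -0.01 at their brightest probe, while another probe of each rose, by 0.79, 0.51 and 0.34. Another probe of Acat2 (-0.07) did not pass. The score difference was 0.44 within slide series 1 and 0.49 within series 2.

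Markers of the Leydig cell, the steroid-making cell between the tubules, moved apart from each other at this dose. Cyp2a1, a steroid hydroxylase, rose by 2.43 ± 0.266 (SE, n = 9 and 9), Prlr, the prolactin receptor, by 1.55 ± 0.163, Vcam1 by 0.92, Hsd11b1 by 0.77 and Insl3, a peptide hormone of the Leydig cell, by 0.47 ± 0.123. The receptor of luteinising hormone, Lhcgr, had a log2 fold of 0.02 ± 0.280 (adjusted p = 0.980), Nr5a1 of 0.49 (adjusted p = 0.0718), Nr2f2 of -0.10 and Nr0b1 of -0.16, and none of these passed. In all, 5 of 14 members of the Leydig cell identity list rose, 6 when adjusted over the list alone, and the list median was 0.13 (camera adjusted p = 6.51e-06; adjusted p = 0.00520 with an estimated correlation). The score difference was 0.44 within slide series 1, 0.52 within series 2 and 0.51 with slide as a block.

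Antioxidant and detoxifying genes also rose at 30 mg/kg/day. In the oxidative stress and glutathione list 8 of 17 members rose, 9 when adjusted over the list alone, with Cat, the catalase gene, at 0.80, Gsta2 and Gsta3, of the glutathione transferases, at 0.72 and 0.67, and Prdx1 at 0.44. The list median was 0.21 (camera adjusted p = 2.94e-07; adjusted p = 1.41e-04 with an estimated correlation). Of 6 measured genes of the aryl hydrocarbon receptor and xenobiotic list, Cyp1b1 (1.09 ± 0.107) and Ugt1a6 (0.83 ± 0.132), both known targets of that receptor, rose. In all, 4 of the 6 had log2 folds above 0, and the median was 0.08 (camera adjusted p = 0.00818, and adjusted p = 0.0320 with an estimated correlation). Tiparp, another member, did not pass at any probe (log2 folds -0.02, -0.20 and -0.15), so the rises do not show activity of the receptor. For the aryl hydrocarbon receptor and xenobiotic list at 30 mg/kg/day the call ended when the median over the probes of a gene was taken (adjusted p = 0.0662) and in slide series 1 alone (adjusted p = 0.0621). The score differences within slide series 1 and 2 were 0.25 and 0.32 for the oxidative stress list and 0.28 and 0.36 for the aryl hydrocarbon receptor list.

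The spermatid lists were slightly lower at 30 mg/kg/day, and the tests disagreed on whether they passed. The round spermatid list had a median of -0.11 (camera adjusted p = 0.00744), with 1 member of 12 lower, Tssk2, a kinase of spermatids, at -0.17, and 3 lower when adjusted over the list alone. The elongating spermatid list had a median of -0.10 (camera adjusted p = 0.00719) with 0 of 16 members past the threshold in limma, 2 at an unadjusted p under 0.05, and all 16 below 0. By exact permutation the round spermatid score was lower by 0.12, with 0 of 9 rats above the control mean (adjusted p = 0.00426), and the elongating spermatid score was lower by 0.11 (adjusted p = 0.0535), while fry gave adjusted p = 0.00166 and adjusted p = 0.0123. Neither camera call held with an estimated correlation (adjusted p = 0.175 for round and adjusted p = 0.326 for elongating spermatids), and quantile normalization ended that of the elongating spermatid list at 30 mg/kg/day (adjusted p = 0.232). Within slide series 1 and 2 the score differences were -0.12 (exact p = 0.0303) and -0.13 (exact p = 0.0286, the smallest possible) for round and -0.11 and -0.11 for elongating spermatids, and the camera call of the round spermatid list at 30 mg/kg/day ended in series 1 alone (adjusted p = 0.0621). The spermatogonia list (median -0.05, adjusted p = 0.598), the meiotic spermatocyte list (-0.05, adjusted p = 0.255; Msh5 rose by 0.33) and the mitotic cell cycle list (-0.05, adjusted p = 0.317) were not past the threshold.

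Lists of Sertoli cells and of genes that androgens control in them were not past the threshold at 30 mg/kg/day. The Sertoli cell list had a median of -0.02 (adjusted p = 0.706), with Aldh1a1, which makes retinoic acid, higher by 1.17, Inha, the inhibin alpha subunit, higher by 0.24, and Gata1 lower at -0.32. The list of androgen dependent Sertoli genes had a median of -0.03 (adjusted p = 0.762), and Rhox5, a homeobox gene that androgens induce in Sertoli cells, had a log2 fold of -0.01 ± 0.111 (SE, n = 9 and 9). The macrophage list (0.15, adjusted p = 0.0503; Cd68 and Laptm5 rose) did not pass but lay at the threshold, and it passed in 19 of the 42 fits that left out 1 rat (adjusted p = 0.00832 to 0.0499). Others that did not pass were vascular endothelium (0.12, adjusted p = 0.0972; Kdr, Emcn and Egfl7 rose; adjusted p = 0.0278 to 0.0467 in 3 fits that left out 1 rat), immediate early and heat shock (0.14, adjusted p = 0.255; Fos, Jun and Ier2 rose), apoptosis (0.07, adjusted p = 0.403), lymphocyte (0.07, adjusted p = 0.523), erythroid cell (0.06, adjusted p = 0.676) and peritubular myoid and smooth muscle (-0.07, adjusted p = 0.627). The same holds for gonadal hormone receptors and feedback (0.00, adjusted p = 0.523; Igf1 rose and Thrb fell), epididymis (-0.04, adjusted p = 0.627; Rnase10 was at least 1.51-fold higher, well above background on 3 of 9 control arrays) and adipose tissue (-0.01, adjusted p = 0.927). In the cAMP and LH response list (adjusted p = 0.676), Cebpb rose while the median was -0.04, the mean 0.14 and the direction of the test up. The test also pointed up against a median below 0 for Sertoli cell (mean 0.05), epididymis (mean 0.11) and adipose tissue (mean -0.02). Exact permutation of list scores, which asks whether rats differ and not whether a list differs from other genes, passed among these lists for cAMP and LH response (difference 0.14, adjusted p = 0.00946) and immediate early and heat shock (0.13, adjusted p = 0.0305).

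**Figure D2:**
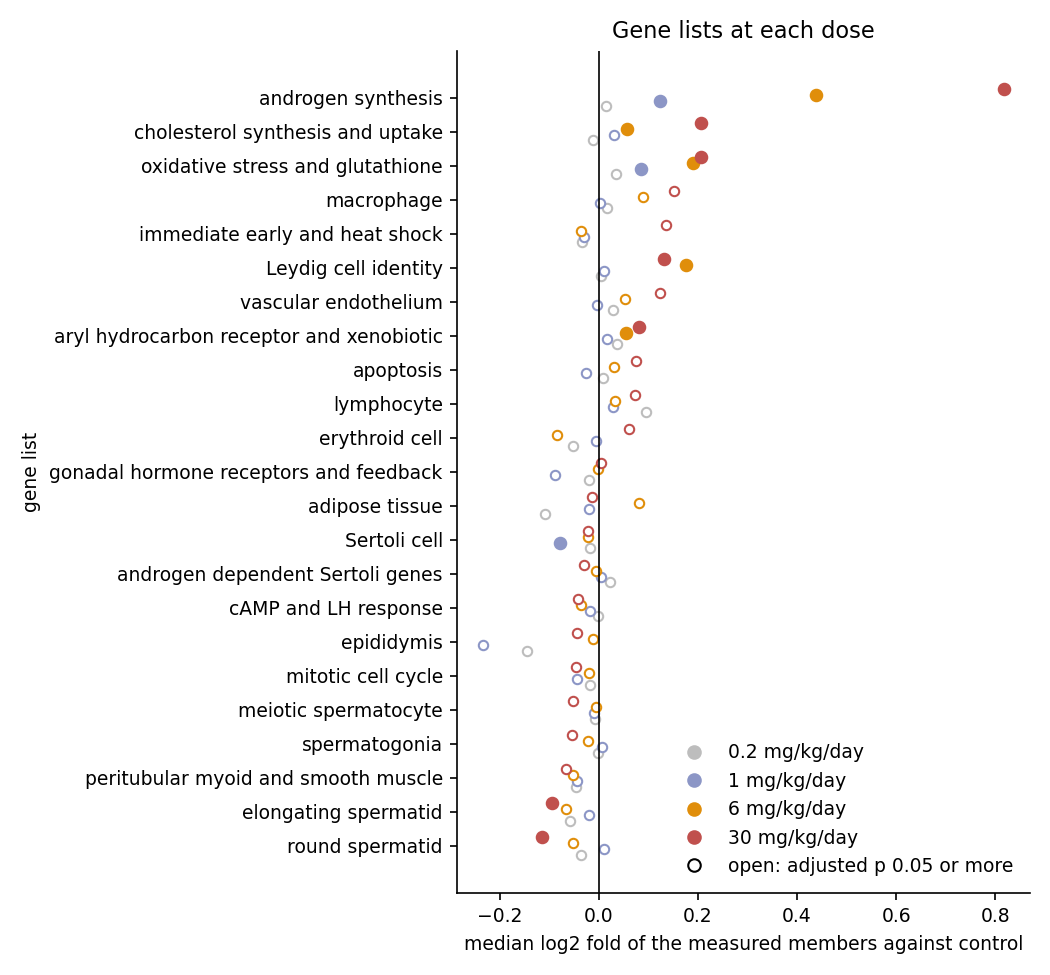
Median log2 fold against control of the measured members (horizontal axis) of each of the 23 gene lists (vertical axis), with 1 point per dose, colored by dose. Filled points had a camera adjusted p under 0.05. The androgen synthesis list stood at 0.82 at 30, 0.44 at 6, 0.12 at 1 and 0.01 at 0.2 mg/kg/day.

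The 10 rising genes that the rule named by log2 fold at 30 mg/kg/day were not enzymes of androgen synthesis. Gpr83 (2.99 ± 0.327, SE, n = 9 and 9), Igfbp4 (2.98 ± 0.227; 2.34 at another probe), which binds insulin-like growth factors, and Mrap (2.80 ± 0.166; genome build rn4, chromosome 11, 30731199 to 30731258), which carries the adrenocorticotropin receptor to the cell surface, were well above background on all 18 arrays. The other 7 were not well above background on some or all control arrays, so only a lower bound of their fold is given, and their order among themselves and against Cyp11a1 is open. Scd, which desaturates stearic acid, was at least 11.6-fold higher (well above background on 3 of 9 control arrays), Degs1l2 at least 10.8-fold (8 of 9), Fabp6, a binding protein for bile acids, at least 9.18-fold (0 of 9; chromosome 10, 28694853 to 28695787), Gdf15, a stress-induced cytokine, at least 7.18-fold (3 of 9), Nrsn1 at least 6.73-fold (5 of 9; log2 fold 1.74 at another probe), Stc2, a secreted glycoprotein, at least 5.96-fold (2 of 9) and Miox, myo-inositol oxygenase, at least 2.52-fold (0 of 9).

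Among the genes that fell, Calb2, the calcium-binding protein calretinin, fell by 1.92 (SE 0.253, n = 9 and 9; chromosome 19, 40023194 to 40023254; adjusted p = 4.27e-07), Igfbp3, another binding protein of insulin-like growth factors, by 1.07 (SE 0.174) and B3gnt7 by 0.96 (SE 0.191). Ces1c, a carboxylesterase, fell by 1.89 at 1 probe and rose by 0.78 at another. Ctdp1 was at least 1.94-fold lower (8 of 9 arrays well above background at 30 mg/kg/day), but its other 2 probes had log2 folds of -0.10 and 0.01, and Myrip was at least 1.7-fold lower (5 of 9 arrays; log2 fold of the other probe -0.08). Nr5a2, a nuclear receptor, fell by 1.27 with an adjusted p of 0.0468, which was 0.0988 with slide as a block and above 0.05 in 23 of the 42 fits that left out 1 rat, at most 0.115. Erc1, Pigg and Uspl1 also passed downward but lay near background, with 3, 1 and 2 of 9 arrays well above it at 30 mg/kg/day and 4, 0 and 4 of 9 in controls, so no fold is given. In fits that left out 1 rat the call of Erc1 ended 9 times (adjusted p up to 0.117) and that of Pigg 6 times (adjusted p up to 0.0749). With slide as a block Pigg no longer passed (adjusted p = 0.0852), while Erc1 did (adjusted p = 0.0324).

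In limma, the 2704 probes changed at 30 mg/kg/day made up 8.49% of the 31839 tested, 57.9% of them were higher, and 1565 genes with a symbol were among them. The change was at least 2-fold for 186 higher and 14 lower probes, and the median size was 0.45 for the higher and -0.38 for the lower probes. With slide as a block 2600 probes passed, and 1047 and 412 did within slide series 1 and 2 alone. Of the 2704 probes, which were chosen on these same arrays, 2704 had the same direction within series 1 and 2703 within series 2. Without rats 3 and 7, 2726 probes passed, and without rats 3, 7 and 9, 2491.

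**Figure D3:**
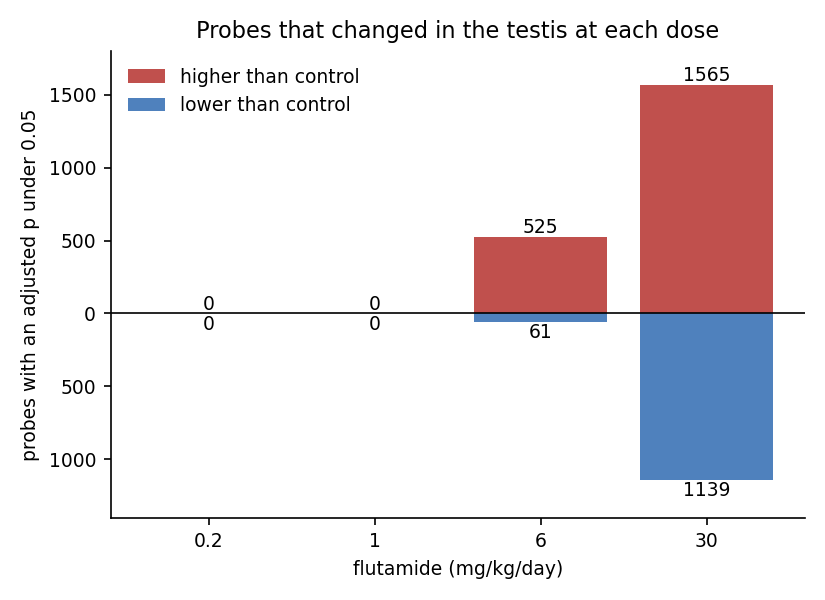
Number of probes with an adjusted p under 0.05 (vertical axis) at each dose in mg/kg/day, with bars above 0 for probes higher and below 0 for probes lower than control. The counts were 0 and 0 at 0.2 and at 1, 525 and 61 at 6, and 1565 and 1139 at 30 mg/kg/day.

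At 6 mg/kg/day the same genes of the route to testosterone rose by smaller amounts. Cyp11a1 rose by 1.69 ± 0.175 (SE, n = 9 and 9; adjusted p = 2.37e-08), Scarb1 by 1.40 ± 0.176, Star by 1.33 ± 0.222, Hsd3b1 by 1.07 ± 0.179 and Cyp17a1 by 1.07 ± 0.166. Cyp2a1, the Leydig cell hydroxylase, rose by 2.25 ± 0.266 (adjusted p = 3.57e-07) and Igfbp4 by 2.06 ± 0.227 (1.38 at another probe), and Fabp6 was at least 2.26-fold higher. Calb2 fell by 1.15 (SE 0.253; adjusted p = 0.00576).

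In the androgen synthesis list 9 of 13 members rose at 6 mg/kg/day, 10 when adjusted over the list alone (another probe of Hsd3b2 did not pass, adjusted p = 0.551), with a median of 0.44 (camera adjusted p = 1.01e-20; adjusted p = 4.14e-08 with an estimated correlation). Its score was 0.61 ± 0.0967 (SD, n = 9), above every control in 9 of 9 rats (exact p = 4.11e-05), and the difference was 0.58 within slide series 1 and 0.65 within series 2. The oxidative stress and glutathione list (median 0.19, 6 of 17 members higher; adjusted p = 3.27e-08), the Leydig cell identity list (0.18, 4 of 14; adjusted p = 2.45e-06), the cholesterol list (0.06, 5 of 24; adjusted p = 4.50e-06) and the aryl hydrocarbon receptor list (0.05, 2 of 6; adjusted p = 0.00773) also rose. Adjusted over the list alone, 9, 4, 6 and 2 members of these lists rose. All 5 calls held with an estimated correlation, at adjusted p from 4.14e-08 to 0.0240. The score differences within slide series 1 and 2 were 0.20 and 0.27 for the oxidative stress list, 0.33 and 0.43 for Leydig cell identity, 0.16 and 0.21 for cholesterol and 0.20 and 0.29 for the aryl hydrocarbon receptor. The call of the aryl hydrocarbon receptor and xenobiotic list at 6 mg/kg/day ended with the median over the probes of a gene (adjusted p = 0.0618) and in slide series 1 alone (adjusted p = 0.137). No germ cell, Sertoli cell, blood cell or other list was past the threshold, the nearest being elongating spermatid (median -0.07, adjusted p = 0.0596), which passed in 7 of the 42 fits that left out 1 rat (adjusted p = 0.01 to 0.0454). The median, mean and direction of test differed in sign for the Sertoli cell list (-0.02, 0.02, up), epididymis (-0.01, 0.15, up), androgen dependent Sertoli genes (-0.01, 0.01, down) and a few others near 0, none of which passed. By exact permutation the erythroid cell score was lower at 6 mg/kg/day (difference -0.17, adjusted p = 0.00851; camera adjusted p = 0.118), with Hbb and Hbb-b1 lower when adjusted over the list alone.

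Other genes that rose at 6 mg/kg/day were Cyp2a3 (1.67 ± 0.228), Nrsn1 (at least 3.77-fold, with 5 of 9 control arrays well above background; log2 fold 1.07 at another probe), Degs1l2 (at least 3.31-fold, 8 of 9), Scd (at least 2.38-fold, 3 of 9), Stc2 (at least 1.94-fold, 2 of 9) and Gdf15 (at least 1.53-fold, 3 of 9). The falling genes after Calb2 were Ces1c (-1.12 at 1 probe and 0.90 at another), Zfp638 (-0.65), Zfp800 (-0.50), Edrf1 (-0.50), Ifitm3 (-0.45), Zfp711 (-0.43), Stap2 (-0.42), Mpzl2 (-0.41) and Pik3r3 (-0.39). With slide as a block, Zfp638, Zfp800, Edrf1, Ifitm3, Zfp711 and Stap2 no longer passed, at adjusted p from 0.0817 (Edrf1) to 0.154 (Zfp711). Their folds moved little in that fit (-0.64, -0.46, -0.49, -0.45, -0.41 and -0.42 in the same order). The other probes of Zfp638, Zfp800, Edrf1 and Mpzl2 did not pass either. In fits that left out 1 rat, calls ended for Ifitm3 and Zfp711 in 10 of 42 (adjusted p up to 0.0889 and 0.109), Zfp800 in 6 (0.0716), Zfp638 in 4 (0.0609), Edrf1 in 3 (0.0599), Stap2 in 3 (0.0678) and Pik3r3 in 1 (0.0611, without rat 5 of the 6 mg/kg/day group).

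In limma, there were 586 probes changed at 6 mg/kg/day, 525 higher and 61 lower, with 402 genes with a symbol, and 48 higher and 3 lower by at least 2-fold. With slide as a block the count was 384, with 351 higher and 33 lower. Within slide series 1 and 2 alone it was 137 and 24.

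Most of what changed at 6 mg/kg/day also changed at 30. Of the 525 probes higher at 6 mg/kg/day, 515 were also higher at 30, where 25.8 would be shared if the lists were independent, and 57 of 61 were lower at both (2.18 if independent). Among the probes higher at both, the median log2 fold was 0.48 at 6 and 0.72 at 30 mg/kg/day, and the median ratio 0.698. Because both doses share the controls, part of this overlap comes from them. The correlation of log2 folds across 31839 probes was 0.734 for these doses, against 0.498 on average and 0.699 at most in 100 random regroupings with shared controls. With separate controls for each dose, split by odd and even rat numbers, it was 0.212 and 0.356, and genes are not independent replicates. The odd numbered controls all lay in slide series 1, while 3 of the 4 even ones, rats 4, 6 and 8, lay in series 2. These values thus also carry any difference between the series.

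A direct comparison of 30 with 6 mg/kg/day found further rises. Scd was higher by 2.29 ± 0.326 (SE, n = 9 and 9), Gdf15 by 2.23 ± 0.359 and Fabp6 by 2.02 ± 0.323. Miox was at least 3.05-fold and Stc2 at least 3.07-fold higher (3 and 7 of 9 arrays well above background at 6 mg/kg/day). Degs1l2 (1.71), Gpr83 (1.60), Padi2 (1.60), which converts arginine to citrulline in proteins, Gmpr (1.44) and the metalloproteinase Mmp24 (1.30) were also higher. Apoc1, an apolipoprotein, was lower by log2 fold -0.69, Krt36 by -0.44, Rdx by -0.34, Ccdc91 by -0.32 and Ddi1 by -0.22. The gene named Sp5 was lower by -1.10, but the files describe its probe as similar to a myosin, so its identity is uncertain, and other probes of Rdx (0.25) and Ccdc91 (-0.28 and -0.01) did not pass. Against control, Ccdc91 at 30 mg/kg/day lost its call in 9 of the 42 fits that left out 1 rat (adjusted p up to 0.0914).

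The score of the androgen synthesis list was 1.08 ± 0.155 (SD, n = 9) at 30 and 0.61 ± 0.0967 (n = 9) at 6 mg/kg/day (difference 0.47, exact p = 4.11e-05, the smallest possible; adjusted p = 9.46e-04 over 23 lists). The cholesterol list differed by 0.28 (exact p = 1.65e-04, adjusted p = 0.00189). For the Leydig cell identity list the difference of 0.11 was within the spread between rats (exact p = 0.168, adjusted p = 0.443), as was that of the oxidative stress list (0.05, exact p = 0.193, adjusted p = 0.443). In limma 113 probes were higher and 9 lower at 30 than at 6 mg/kg/day. All 113 were also higher at 30 mg/kg/day than in controls, 70 were higher at 6 as well, and 8 of the 9 were lower at 30 than in controls. The number of probes differing between 30 and 6 mg/kg/day was 115 with slide as a block, 33 and 3 within slide series 1 and 2 alone, 77 without the 30 mg/kg/day rats 3 and 7 and 90 without rats 3, 7 and 9.

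At 1 mg/kg/day no single gene passed, while the androgen synthesis list was shifted upward as a group. The list median was 0.12 with 11 of 13 members above 0, and the score was 0.17 above the control mean. In 5 of 7 rats it lay above every control and in 7 of 7 above the control mean. Cyp11a1 had the largest log2 fold in the list, 0.70 ± 0.187 (SE, n = 7 and 9; limma adjusted p = 0.780), and was the 1 member that rose when adjusted over the list alone (limma adjusted p = 0.00701).

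The camera adjusted p of this list was 4.20e-04, and adjusted p = 0.0278 with an estimated correlation. By exact permutation of the score p was 0.00184 and the adjusted p 0.0422, while fry, which asks whether the members move on balance, gave an adjusted p of 0.115. The difference was 0.20 within slide series 1 (5 and 6 rats, exact p = 0.00649), 0.09 within series 2 (2 and 3 rats, exact p = 0.3 where 0.1 is the smallest possible) and 0.16 with slide as a block. The oxidative stress list rose (median 0.09, 0 of 17 members past the threshold in limma, 1 at an unadjusted p under 0.05; adjusted p = 0.0400) and the Sertoli cell list fell (median -0.08, 0 of 19 members past it and 0 at an unadjusted p under 0.05; adjusted p = 0.0424). Neither held with an estimated correlation (adjusted p = 0.149 and adjusted p = 0.442) or with slide as a block (adjusted p = 0.0891 and adjusted p = 0.592). In fits that left out 1 rat the oxidative stress call ended without control rats 4, 6, 8 or 9 or rats 2 or 5 of the dose (adjusted p up to 0.223), and the Sertoli cell call in 11 of 42 (adjusted p up to 0.237). Next came cholesterol synthesis (median 0.03, adjusted p = 0.0582), which passed in 7 of the 42 fits that left out 1 rat (adjusted p = 0.0199 to 0.0447).

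In limma 0 probes passed at 1 mg/kg/day, and 792 had an unadjusted p under 0.05. The smallest adjusted p was 0.0871, for Slc16a11, a carrier of the monocarboxylate family, with a log2 fold of 0.82 ± 0.150 (SE, n = 7 and 9), followed by Cyp2a1 (1.35 ± 0.285, adjusted p = 0.409) and Igfbp4 (1.11 ± 0.243, adjusted p = 0.409). These 3 were named after their values were seen. Slc16a11 rose by 1.35 at 6 and by 1.74 at 30 mg/kg/day. It passed at 1 mg/kg/day in 4 alternative fits (adjusted p = 0.0150 to 0.0446), among them the one with slide series as a block. With 1 rat left out, 1 probe passed without control rat 1, without rat 1 of this dose or without rat 7 of 30 mg/kg/day. In simulated data of this size, limma called 60% of genes changed 1.5-fold and 86% of genes changed 2-fold at this dose. Many genes were changed together there, so these shares may be too high for the real data. Cyp2a1 and Igfbp4, above 2-fold in the real data, did not pass.

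At 0.2 mg/kg/day no gene or list was past the threshold. The androgen synthesis list had a median of 0.01 and a score of 0.03 ± 0.109 (SD, n = 8) above the controls (exact p = 0.543, adjusted p = 0.828), and Cyp11a1 and Star did not pass. By camera the nearest list was elongating spermatid (median -0.06, camera adjusted p = 0.0596; adjusted p = 0.538 with an estimated correlation), and it passed with slide as a block (median -0.07, adjusted p = 0.0199). It also passed in 5 fits that left out 1 rat (adjusted p = 0.00274 to 0.0146), without control rats 1, 2 or 4 or rats 4 or 8 of this dose. Within slide series 1 and 2 its score difference was -0.06 (exact p = 0.240) and -0.03 (exact p = 0.5), and over both the exact p was 0.234 (adjusted p = 0.802). By exact permutation the nearest list was oxidative stress and glutathione, with a score difference of 0.05 and 8 of 8 rats above the control mean (exact p = 0.00675, adjusted p = 0.155; camera adjusted p = 0.195). Of all list members, Abcb1b alone, a drug transporter, passed when adjusted over the list alone (log2 fold -0.37, limma adjusted p = 0.0396). In limma 0 probes passed and 608 had an unadjusted p under 0.05. In simulated data limma called 68% of genes changed 1.5-fold and 78% of genes changed 2-fold at this dose, so smaller changes could go undetected. As at 1 mg/kg/day, these shares may be too high for the real data.

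**Figure D4:**
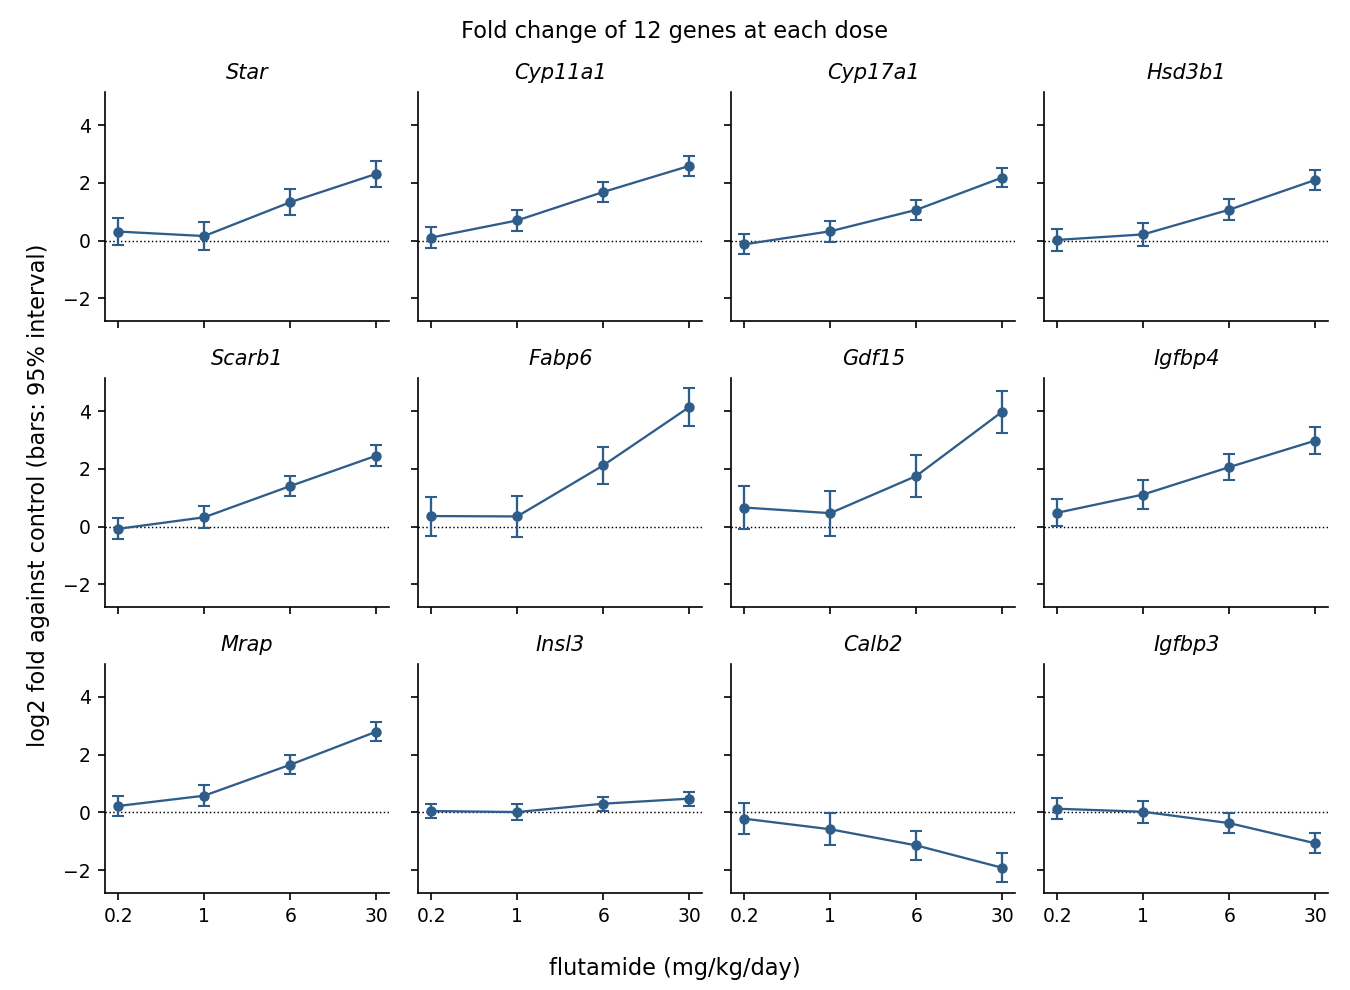
Log2 fold against control (vertical axes, points, with bars for 95% intervals) of 12 genes at the 4 doses (horizontal axes, mg/kg/day). Cyp11a1 stood at 0.70 at 1, 1.69 at 6 and 2.59 at 30 mg/kg/day, and Insl3 at 0.47 at 30. Fabp6 and Gdf15 were not well above background on all or some control arrays, so the size of their folds is uncertain.

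Across all 5 groups, many probes had a slope over the dose scores, which a change at the highest doses alone can also give. The 10 rising genes that the rule named by slope were those it named at 30 mg/kg/day. Of these, Igfbp4, Gpr83 and Mrap were well above background on all control arrays, while the slopes of Fabp6, Scd, Gdf15, Stc2, Degs1l2, Nrsn1 and Miox are limited by background in controls, so their rank is open. The falling side held Calb2, Ces1c, Ctdp1, Igfbp3, B3gnt7, Myrip, Erc1 and Pigg, and added Thbd, the thrombin receptor thrombomodulin, at -0.88 (30 mg/kg/day against control, SE 0.180, adjusted p = 7.60e-04), and Nusap1, a protein of the mitotic spindle, at -0.93 (adjusted p = 0.0501). Nusap1 was under 0.05 in 8 of the 42 fits that left out 1 rat and with slide as a block (log2 fold -0.99, adjusted p = 0.0398). In limma there were 3298 probes with a dose trend, a slope over dose scores 0 to 4, 1864 rising and 1434 falling, and 2573 of these were called at 30 mg/kg/day. The F-test over the 4 doses gave 1590 probes differing among the 5 groups, 1559 of which also had a trend. With slide as a block the counts were 3029 and 1328, within slide series 1 alone 1215 and 536, and within series 2 alone 1120 and 205. The trend over control, 0.2 and 1 mg/kg/day alone passed for 0 probes in limma, with 1115 at an unadjusted p under 0.05, and without the 30 mg/kg/day group for 920.

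Across all probes, the correlation of the folds at 0.2 and at 1 mg/kg/day with those at higher doses lay within the range of random regroupings with shared controls. It was 0.464 between 0.2 and 1 mg/kg/day, 0.504 between 0.2 and 6, 0.406 between 0.2 and 30, 0.529 between 1 and 6, and 0.50 between 1 and 30. The random regroupings averaged 0.458, 0.479, 0.472, 0.471 and 0.487 for these pairs and reached 0.662, 0.701, 0.731, 0.653 and 0.669. With the controls split, odd rat numbers for the lower dose, they were -0.214, -0.0475, -0.0787, 0.0451 and 0.0432. This split of the controls nearly followed the slide series, so a difference between the series enters these values. Probes called at 30 mg/kg/day are a small share of these, so the values do not exclude a smaller response of those probes at 0.2 or 1 mg/kg/day.

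The authors' deposited list of dose-responsive probes held 1585 probes, 1583 of which were tested here. Since it was chosen on these arrays, it is not independent evidence. Of the 1583, 1460 passed the F-test and 1552 the dose trend. At 30 mg/kg/day 1554 were called, with 1083 above and 500 below control by sign, at 6 mg/kg/day 541, and at 1 and at 0.2 mg/kg/day 0 in limma, with 248 and 77 at an unadjusted p under 0.05. A further 130 probes passed the F-test, and 1150 were called at 30 mg/kg/day, without being in the authors' deposited list.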

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

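The tests of explanations and the counts over other splits of the rats were chosen after the results they concern had been seen, while the rule for outlying rats was fixed earlier.

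The rise of the androgen synthesis list at 30 mg/kg/day was weighed against 3 technical or compositional causes. A larger share of Leydig cells in the tissue would raise markers read from Leydig cells alone by about the same amount. For 9 of the 14 Leydig cell identity members the 95% interval ended below the androgen synthesis median of 0.82. The androgen score exceeded the Leydig score by 0.60 more than in controls (exact permutation p = 4.11e-05). Members that other cells also express would rise less in any case. The list was not checked for such members, so these values do not exclude a larger share. A difference between slides would shrink with slide as a block, where the score difference was 1.096 against a control SD of 0.0818. The scaling of the arrays left a lowest median of 0.82 over 3 other scalings. A higher RNA level of these genes per Leydig cell may account for the rise, and a part of a change in cell share stays open. What set it off stays open. Hormone levels were not analysed here. The cAMP and LH response list had a score difference of 0.0026 at 6 mg/kg/day (exact permutation p = 0.955), where the androgen score was 0.61. At 30 mg/kg/day its score difference was 0.14 (exact permutation adjusted p = 0.00946) with a median of -0.04 (camera adjusted p = 0.676). This list was read in whole testis after 28 days and not checked for members that other cells express. Its values therefore do not decide whether luteinising hormone took part.

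The smaller rise of the same list at 1 mg/kg/day was weighed against chance, slides, single rats and cell share. Chance among these rats gave an exact two-sided permutation p of 0.00184, a difference between slides left an adjusted p of 0.0117 with slide as a block, and the highest adjusted p with 1 rat left out was 0.0369. Against this, fry gave an adjusted p of 0.115 and the list did not pass in slide series 2 alone, which held 2 rats of this dose. A larger share of Leydig cells stays open at this dose. The Leydig cell identity score was 0.11 above controls, in 7 of 7 rats above the control mean (exact p = 0.0365, adjusted p = 0.168). The androgen score exceeded it by 0.06 more than in controls (exact p = 0.336), so the 2 scores could not be separated. The Leydig list median was only 0.01, with 9 of 14 members above 0, against 0.12 for androgen synthesis. Cyp2a1, at 1.35, thus weighs heavily in the Leydig score, and the comparison was not run without it. A weaker form of the response at higher doses may also explain the rise, as a hypothesis found and tested on the same rats.

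For the 1139 probes lower at 30 mg/kg/day, a main axis of variation among the control, 0.2 and 1 mg/kg/day rats was weighed first. It was the first principal component of their residuals, with 12.9% of the variance. It was not set against any measure of RNA or array quality, so a difference in quality off this axis is not excluded. The axis was found without the 30 mg/kg/day rats, which stood at -4.55 ± 20.16 on it (SD, n = 9; control mean 0, SD 26.84; 95% interval of the difference -28.42 to 19.32). Even at the limit of that interval the axis would account for a median fall of -0.0588, against the -0.38 seen. Since the axis hardly moved with dose, using it as a covariate could not move the folds much and is not counted as a test. Dilution of germ cell RNA by the RNA of genes that rose, if it gave the whole of this fall, would lower germ cell genes by about that amount. The interval of 47 of the 51 germ cell list members lay above -0.38, and their median was -0.09. The -0.38 belongs to probes chosen for passing, which enlarges it. A smaller dilution is not excluded, since the round and elongating spermatid lists had medians of -0.11 and -0.10. With the 2 rats that stand apart from the others of their group, rats 3 and 7, left out together, 1085 probes were still lower. Leaving out the 30 mg/kg/day rats 3, 7 and 9 left 2491 probes changed at 30 mg/kg/day. The number of falls thus did not need these rats. Left out singly, rats 3 and 7 moved the count of changed probes in opposite directions, from 2704 to 2240 and 3309, so each had weight. A lower RNA level of these genes in some cell type may remain as an explanation, and no biological explanation was tested for them.

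In 100 splits of the rats into groups of the real sizes, the real count was the largest in 4 comparisons, 1 of 100, the smallest share these splits can give. These were 6 mg/kg/day (586 probes, highest other 1), 30 mg/kg/day (2704, highest other 2183), the F-test (1590, highest other 314) and the trend (3298, highest other 1). At 30 mg/kg/day 15 other splits had any call, so there the real count stands less far apart. For 30 against 6 mg/kg/day 2 of 100 splits had at least the 122 probes. The other of the 2 had 1174, and 7 other splits had any call. Chance is thus not excluded for a count of this size. For 0.2 mg/kg/day, 89 of 100 splits had at least the 608 probes at an unadjusted p under 0.05 (highest other 2753), and for 1 mg/kg/day 75 of 100 had at least the 792 (highest other 3881), so chance could not be excluded there. The high counts at 0.2, at 1 and for 30 against 6 mg/kg/day, several times the real ones, were extremes. The medians of the other splits were 890, 1075 and 0. A structure of the rats or arrays beyond dose may lie behind the extremes, which was not tested. Arrays of slide series 1 made up 4 of 8 against 7 of 9 in the highest split at 0.2, 6 of 7 against 5 of 9 at 1 and 7 of 9 against 4 of 9 at 30 mg/kg/day, where rats 3 and 7 both lay on the control side, so a part of the slide series, and at 30 mg/kg/day of these 2 rats, stays open. For 30 against 6 mg/kg/day the series were even, 5 of 9 against 5 of 9, and rats 3 and 7 lay on opposite sides.

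In a search of 143 groups of rats, covering array measures, scores of lists that passed and genes named by rule at 6 and 30 mg/kg/day, 13 values lay far from the rest of their group, while chance gives about 1 group in 20. The values are log2 levels less the control mean. The round spermatid score of control rat 2 was -0.13, against -0.03 to 0.07 in the other controls, and this rat is also the control outside the authors' centring. Among controls, Erc1 stood at 2.21 in rat 6, Igfbp3 at -0.87 in rat 3, Myrip at 1.51 in rat 1 and Uspl1 at 2.30 in rat 9. At 6 mg/kg/day, Degs1l2 stood at 0.83 in rat 2, Nr5a2 at -2.88 in rat 7, Uspl1 at -1.48 in rat 2 and B3gnt7 at -1.33 in rat 5. At 30 mg/kg/day, Calb2 stood at -0.99 in rat 4, Zfp711 at -1.43 in rat 3, Stap2 at -0.71 in rat 8 and Ctdp1 at -3.83 in rat 2.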

How the results depend on the processing

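The slide series alternatives, the opposite split of the controls and leaving out rats 3 and 7, or 3, 7 and 9, of 30 mg/kg/day were chosen after seeing the data. Unless a cause is named, the cause was not tested.

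Changed scaling and background left the counts within 1.5 times. For probes changed at 6 mg/kg/day and probes changed at 30 mg/kg/day, quantile normalization gave 612 and 2810, median centring 536 and 2415, series matrix values 556 and 2684, and normexp 404 and 2411. The 0 probes changed at 0.2 mg/kg/day in limma, with 608 at an unadjusted p under 0.05, stayed 0 in every alternative run. The androgen synthesis list passed at 6 and 30 mg/kg/day in all alternatives run. Rat numbers were not taken as pairs, since the sources used here name no block behind them. Residual profiles of rats with the same number correlated by 0.041 on average (25 of 79 pairs over 0.1), those with other numbers by -0.005, and 9 of 42 arrays correlated best with their own number in another group. For arrays on 1 slide the mean was 0.124 over 51 pairs, and 22 of 42 arrays correlated best with one of their slide in another group, so slide had more weight than rat number. Rat number as a replicate block gave 668 and 3069, so a block behind the numbers is not excluded.

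With slide as a block, 384 probes changed at 6 mg/kg/day, 1 list at 0.2 mg/kg/day (elongating spermatid) and 1 at 1 mg/kg/day (androgen synthesis). Array weights gave 947 probes at 6 mg/kg/day and 3 lists at 0.2 mg/kg/day. With series matrix values 1 list passed at 0.2 mg/kg/day. At 1 mg/kg/day, where 792 probes had an unadjusted p under 0.05 and limma called 0, 1 probe passed with the filter well above background on all 42 arrays, 1 with eBayes with trend and robust, 1 with the first residual principal component as a covariate and 1 with slide series as a block (Slc16a11 in each), and 1 with only the groups compared (Sat1).

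With only the groups compared, and so fewer samples, there were 1371 probes changed at 30 mg/kg/day and 36 probes differing between 30 and 6 mg/kg/day. With an adjusted p under 0.01, a stricter threshold, the counts were 337 probes changed at 6 mg/kg/day, 1502 at 30, 74 between 30 and 6, 1012 probes differing among the 5 groups and 1973 probes with a dose trend, and at least 1.5-fold they were 212, 740, 54, 598 and 724. In slide series 1 alone, with fewer samples, they were 137, 1047, 33, 536 and 1215, and in slide series 2 alone 24, 412, 3, 205 and 1120. In slide series 2 alone 3 probes changed at 1 mg/kg/day (Guf1, AI228630 and Yipf7). The trend passed for 0 probes in control, 0.2 and 1 mg/kg/day alone (limma, 1115 at an unadjusted p under 0.05) and for 920 without the 30 mg/kg/day group. Without rats 3 and 7 of 30 mg/kg/day, 77 probes differed between 30 and 6 mg/kg/day, and without rats 3, 7 and 9 it was 90. Of the authors' dose-responsive probes, 541 passed the contrast at 6 mg/kg/day, 0 at 1 and 0 at 0.2 mg/kg/day (248 and 77 at an unadjusted p under 0.05).

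The number of lists at 1 mg/kg/day, 3 as reported, was 1 with camera with an estimated correlation, 0 with fry, 1 with the median over the probes of a gene and 0 in slide series 2 alone. The androgen synthesis list at 1 mg/kg/day had a median of 0.12 and an adjusted p of 0.115 with fry, and 0.11 and 0.542 in slide series 2 alone, while the other 13 alternatives gave adjusted p from 1.99e-04 to 0.0278. The Sertoli cell list at 1 mg/kg/day turned to 0.0072 in slide series 2 alone (adjusted p = 0.953).

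With the controls split by odd and even rat numbers, the correlations of log2 folds were -0.214 for 0.2 and 1 mg/kg/day, -0.0475 for 0.2 and 6, -0.0787 for 0.2 and 30, 0.0451 for 1 and 6, 0.0432 for 1 and 30 and 0.212 for 6 and 30. The opposite split gave -0.111, -0.0928, 0.0122, -0.101, 0.0475 and 0.356. Shared controls are absent in these values by construction. The odd numbered controls were all of slide series 1 and most of the even ones of series 2, so a difference between the series enters them.

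With each rat left out in turn, the counts ranged over 0 to 0 at 0.2, 0 to 1 at 1, 459 to 697 at 6 and 2240 to 3309 at 30 mg/kg/day, 97 to 155 between 30 and 6 mg/kg/day, 1331 to 1786 in the F-test and 2826 to 3746 in the trend. Lists ranged over 0 to 2 at 0.2, 1 to 5 at 1, 5 to 7 at 6 and 7 to 9 at 30 mg/kg/day. At 0.2 mg/kg/day 1 list passed without control rat 1 or 4 or rat 8 of the dose, and 2 without control rat 2 or rat 4 of the dose. At 1 mg/kg/day 1 list was left without control rat 4, 6 or 8 or rat 5 of the dose, and 5 passed without rat 6. The median of the androgen synthesis list ranged over 0.11 to 0.17 at 1, 0.42 to 0.47 at 6 and 0.78 to 0.84 at 30 mg/kg/day. For named genes, 2519 of 2613 such values kept direction and side of the threshold, 85 lost and 9 gained a call, and over the other alternatives these were 418, 16 and 3 of 437. For lists they were 487, 17 and 50 of 554, and 157, 22 and 21 of 201 with 1 in the other direction.

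Scan date as a block was not run, because all arrays were scanned on 1 day, nor were surrogate variables, in place of which the residual component was used. Signal over background limits Erc1, Pigg and Uspl1, for which at most 4 of 9 arrays were well above background in controls and at most 3 of 9 at 30 mg/kg/day.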

Other observations

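All tests in this part were chosen after the results at 30 mg/kg/day had been seen.

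Genes that break down fatty acids stood out among the rises at 30 mg/kg/day. Ehhadh, of the peroxisomal pathway, rose by 1.41, Decr1 by 1.05, Echs1 by 1.02 and Acaa2 and Hadh, of mitochondrial beta oxidation, by 0.78 each. A list of fatty acid oxidation was written after the values of 6 of its members had been seen. Of its 24 members 16 rose (median 0.48), and without the members already seen the camera adjusted p was 8.53e-15 (18 members, median 0.40). A general rise of mitochondrial transcripts in the tissue was set against it, and for 20 of 20 oxidative phosphorylation members the 95% interval ended below 0.48, with a median of 0.01. These values concern the whole tissue, and a rise of mitochondrial transcripts confined to some of its cells is not excluded. A joint rise of genes of fatty acid oxidation is a candidate explanation, and its cell type was not tested.

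Genes that supply NADPH, the reductant that steroid and fatty acid synthesis use, showed a like shift. Tkt rose by 0.67, Me1 by 0.45 and Idh1 by 0.44, and without the members already seen the pentose phosphate and NADPH list had a camera adjusted p of 1.56e-07. In the fatty acid synthesis and desaturation list 7 of 12 members rose, among them Fads1 by 1.14, Fads2 by 0.71, Acly by 0.64 and Elovl6 by 0.62. Fasn (0.13), Acaca (0.06) and Srebf1 (0.10) were among those that did not pass. Without the members already seen the camera adjusted p of this list was 2.65e-07. The list of the amino acid and endoplasmic reticulum stress response did not pass without the members already seen (adjusted p = 0.279), so a stress response behind the rise of Gdf15 and Stc2 remains open. These genes may rise with the demand of steroid synthesis, which was not tested.

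At 1 mg/kg/day the fatty acid oxidation list also passed while no single member was past the threshold (median 0.10, camera adjusted p = 7.70e-11; adjusted p = 9.48e-04 with an estimated correlation; adjusted p = 9.64e-04 without the members already seen). The pentose phosphate and NADPH list passed there too (median 0.10, adjusted p = 6.37e-04; adjusted p = 0.00561 with an estimated correlation; adjusted p = 0.0336 without the members already seen), as did fatty acid synthesis and desaturation (median 0.06, adjusted p = 0.00500, adjusted p = 0.00859 and adjusted p = 0.0469 in the same order), with no single member past the threshold. At 0.2 mg/kg/day none of the 3 lists passed (adjusted p = 0.191 to 0.504). The 3 lists were written after rises at the highest dose had been seen against the same controls. Low values in these controls would raise the folds at 1 mg/kg/day as well, also without the members already seen. Split controls, exact permutation, slide as a block and leaving out 1 rat were not run on these lists. Their calls at 1 mg/kg/day therefore do not separate an effect of dose from such controls.

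Genes of the 30 mg/kg/day response were then followed to lower doses, with the controls used for their choice kept apart from those used for comparison. For 467 rising probes chosen against odd numbered controls, the score at 1 mg/kg/day was 0.17 ± 0.0828 (SD, n = 7) above the even numbered controls, 17.2% of the value at 30 mg/kg/day, above every such control in 7 of 7 rats (exact two-sided p = 0.00606, adjusted p = 0.0146). For 331 probes chosen the other way it was 0.21 ± 0.0834, again in 7 of 7 rats (exact p = 0.00253, adjusted p = 0.00758). Within slide series the exact permutation p was 0.0333 (60 splits) and 0.00794 (252 splits). In the first, control rat 2 was the only control of series 1, and rats 4, 6 and 8 those of series 2. No odd numbered control lay in series 2, so the second covers series 1 alone. Neither value therefore tests the rise well in both series. At 0.2 mg/kg/day the scores were 0.07 and 0.08 (exact p = 0.182 and 0.0948), which decides nothing at this number of rats. The falling probes gave -0.15 (exact p = 0.0455, adjusted p = 0.0909) and -0.06 (exact p = 0.456) at 1 mg/kg/day. A smaller rise of the same genes at 1 mg/kg/day may be present that single probes did not show.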
